A study of Gallus gallus with 2 samples.

How the data were processed

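Per the labels' protocols, gonads of female Leghorn embryos at E5 were taken from each side, dissociated with trypsin-EDTA, passed through a 40 µm strainer, depleted of dead cells and run on the 10x Chromium Next GEM 3′ v3.1 kit. There was 1 library of left and 1 of right gonads. The deposited files hold raw UMI counts per gene and barcode for barcodes called as cells, with 24167 genes in the same order in both libraries. Per the submitters' processing notes, Cell Ranger 6.1.1, Seurat 4 and the genome build GRCg6a were used; no settings were stated, and no filter beyond the calling of cells is recorded. Clusters and their names were built here. Gene names are those of the files, except for names that start with LOC. Such a gene took the symbol that RefSeq gives the same gene, where that symbol was not already in the files. No coordinates are given.

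The classes of markers, the gene lists, the filter, the clustering settings, the rule of size, the named genes and most alternatives were chosen before the data were examined. Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept: 22124 of 23719 left barcodes (93.3%) and 21148 of 25165 right barcodes (84.0%). Doublets were called per library with scrublet in scanpy 1.11.5, at an expected 0.8% per 1000 barcodes (19.0% left, 20.1% right). It called 1112 left (5.03%) and 1738 right barcodes (8.22%), which were removed. The calls lay below the expected shares, so doublets are likely to remain among the 21012 left and 19410 right cells.

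Counts were scaled to 10000 per cell and log-transformed. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1, without integration of the libraries. Genes of the asymmetry, S phase, G2/M and stress lists, and W-linked, ribosomal, mitochondrial and haemoglobin genes, were left out of the variable genes. A cluster took the class with the highest mean log2 level over its markers. It stayed unnamed with too few markers raised 1.5-fold over the median cluster, or with more markers of another class among its 10 leading genes. That scoring was set after the data were seen; the markers were not.

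UMIs were summed over all kept cells, or over a class with at least 100 cells in each library, and divided by the total (CPM, scaled to 1e6). A gene met the rule of size with at least 50 CPM in the higher library, at least 100 UMIs over both and a ratio of at least 2, a library at 0 being set to 3 counts. The genes named are among the 12, of those with a gene symbol, with the largest ratio per direction over all cells and in the coelomic epithelium-like class, and among the 5 largest per direction in other classes, outside haemoglobin, mitochondrial, ribosomal and W-linked genes. Members of the fixed lists were also named, and genes behind counts of 5 or fewer were named in full or in part. CPM carry exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95% and all for counting error only. With 1 library per side no test was run, no p-value was computed and no gene was called changed.

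The 19 gene lists were left-right asymmetry, retinoic acid, oestrogen and steroid, gonadal sex pathway, WNT, BMP and TGF-beta, Hedgehog and Notch, FGF and ERK, epithelium, mesenchyme and matrix, HOX, S phase, G2/M phase, G1 regulators, apoptosis, germ cell, stress and dissociation, hypoxia and glycolysis, and W-linked genes. The median over members with at least 20 UMIs was placed among 10000 random lists of the same size matched on mean expression. Shares of cells with a UMI, and of cells in cycle, were taken after thinning each cell to 2000 UMIs, leaving out shallower cells.

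The scripts were tested on simulated data with 200 changed genes. Intervals covered the true ratio for 95.3% of genes over all cells, 95.2% in the coelomic epithelium-like class and 95.3% in the endothelium-like class. A 2.5-fold change was recovered for 100% of genes over all cells and in the epithelium-like class, and for 90.0% in the endothelium-like class. A 4-fold change was recovered for 100%, 100% and 98.0%, an 8-fold change for 100% in each, and a 1.5-fold change, below the rule, for 0%, 0% and 2.0%. Of the unchanged genes, 0 passed the rule. Both simulated libraries were Poisson draws from the same pooled profile, without sampling of cells, class makeup, free RNA or variation between libraries. The simulation therefore checks the arithmetic and counting error only. It does not tell how many genes pass the rule from those other sources.

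Alternatives covered the barcode filter, doublets, scaling, CPM and ratio minimums, weighting of cells, class makeup, thinning, clustering settings, clustering of each library alone and the minimum UMIs of a list. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Barcodes outside the filter were left out of the comparisons: 1595 on the left with 1.89% of UMIs and 4017 on the right with 6.06%.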

Results

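The data were 2 single-cell RNA-seq libraries (10x Chromium 3′ chemistry, unique molecular identifiers, UMIs) from the gonads of female Leghorn chicken embryos at E5, 1 library of left gonads and 1 of right gonads. The question stated for the series was how the left and right female gonads differ in early differentiation. The labels did not state the number of embryos or whether gonads were pooled. With 1 library per side there was no replicate check on any difference, no test was run, and every interval below covers counting error only. The left library held 23719 barcodes and 65029703 UMIs, with a median of 2246 UMIs and 1326 genes per barcode. The right library held 25165 barcodes and 53076584 UMIs, with a median of 1634 UMIs and 994 genes. Haemoglobin genes took 5.48% of UMIs in the left library and 13.5% in the right. After filtering and removal of called doublets, 21012 left and 19410 right cells were kept, with median depths of 2306 and 1777 UMIs. The left library was the deeper, a gap that bears on every share below. Genes of the W chromosome, which females carry, took 0.322% of left and 0.286% of right UMIs.

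Joint clustering gave 24 clusters, of which 20 took a class name from markers fixed beforehand. Each class name means "like" that type only. The coelomic epithelium-like class was held by different clusters on the 2 sides: clusters 1, 6 and 11 held most of it in the left library and clusters 8 and 2 in the right, with cluster 4 held by both. The gonadal mesenchyme-like class was likewise held mainly by clusters 5 and 9 on the left and clusters 7 and 10 on the right. Left cells made up 96.4% of cluster 1, 94.6% of cluster 6 and 97.51% of cluster 13, but 4.38% of cluster 7 and 2.69% of cluster 8, so each of these 5 may stand for a library as much as for a cell type. The supporting precursor-like class was 1 cluster. Clusters 3, 13, 15 and 19 stayed unnamed and together held 15.1% of left and 10.6% of right cells. In turn they held 7.19%, 5.60%, 0.861% and 1.49% of left cells, and 6.41%, 0.155%, 2.81% and 1.26% of right cells.

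The first comparison asked how the makeup of the left and right libraries differed. Coelomic epithelium-like cells made up 47.4% of left cells (exact 95% binomial interval 46.7 to 48.1) and 32.2% of right cells (31.5 to 32.8), a log2 ratio of 0.56 that ranged from 0.14 with clustering at resolution 2 to 1.28 among cells of at least 2000 UMIs. Gonadal mesenchyme-like cells made up 14.3% on the left (13.9 to 14.8) and 27.8% on the right (27.2 to 28.5). Its log2 ratio of -0.96 moved to -0.080 with clustering at resolution 0.5, -0.27 after thinning, -0.38 under the stricter barcode filter and -0.43 with each library clustered alone. The size of this gap also rests on leaving out unnamed cluster 3, with 1510 left and 1244 right cells. The best score of cluster 3 was for this class, with 10 of 11 markers raised, but its leading genes held more markers of another class. Supporting precursor-like cells made up 13.2% (12.8 to 13.7) and 11.4% (10.9 to 11.8), a direction that turned from 0.22 to -0.28 on the log2 scale under the stricter barcode filter and to -0.22 after thinning. Germ cell-like cells numbered 791 of the left cells (3.77%, interval 3.51 to 4.03) and 270 of the right (1.39%, 1.23 to 1.57), a 2.71-fold higher share on the left. That log2 ratio of 1.44 moved to 0.67 under the stricter barcode filter and to 0.75 after thinning. Germ cell-like cells were deep, with medians of 10731 UMIs on the left and 9765.5 on the right, so a depth limit removes mostly other cells, and more of them from the shallower right library.

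Cells of blood and adjoining tissue were more frequent in the right library. Erythroid-like cells made up 2.98% of left and 7.33% of right cells, endothelium-like cells 1.25% and 2.17%, and neural crest or chromaffin-like cells 0.923% and 2.30%. Mesonephric epithelium-like cells made up 0.581% on the left (0.482 to 0.693) and 2.61% on the right (2.39 to 2.85), 4.50-fold higher on the right. Interrenal or steroidogenic-like cells were 5.10-fold higher on the right (0.262% against 1.33%), and macrophage-like cells 5.18-fold (0.133% against 0.690%). The interrenal direction rests on leaving out unnamed cluster 13, with 1176 left and 30 right cells, whose best score was for that class but with too few markers raised to name it. The smooth muscle-like cluster held 40 right cells and 0 of the 21012 left cells, which allows a left share of up to 0.0143% by a floor of 3 counts (0.0176% by the exact interval). This depended on the clustering: with each library clustered alone the class took 0 left and 872 right cells, but it took 1.49% of left and 1.63% of right cells at resolution 0.5, and 5.46% and 4.67% with all variable genes used, so no side difference is read from it.

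**Figure D1:**
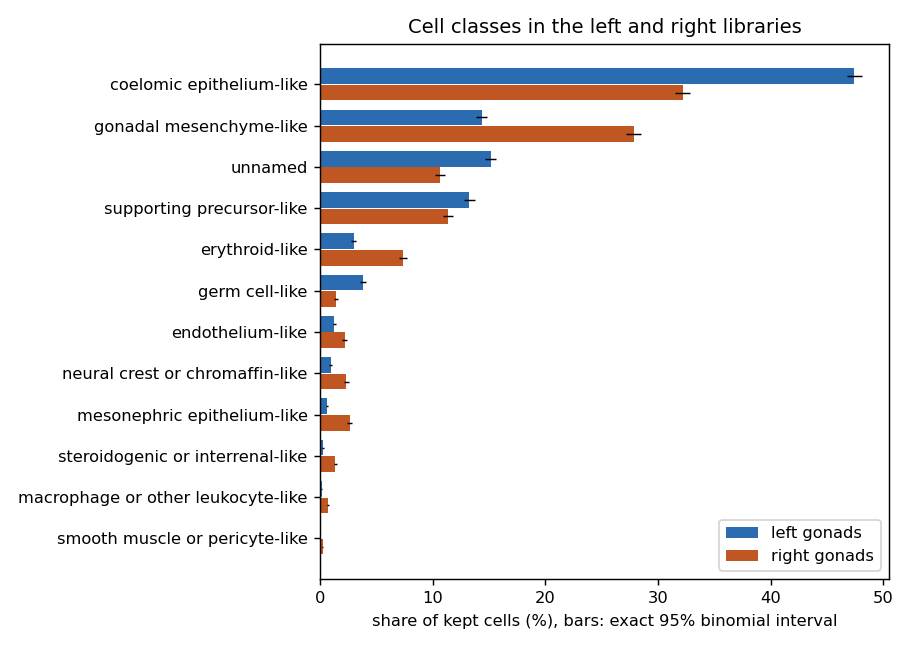
Share of kept cells (percent) per class in the left (blue) and right (orange) libraries, with exact 95% binomial intervals that cover counting error only. Coelomic epithelium-like cells took 47.4% on the left against 32.2% on the right, and gonadal mesenchyme-like cells 14.3% against 27.8%.

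UMIs summed over all kept cells were 60399923 on the left and 45813096 on the right. A gene met the rule of size when it had at least 50 CPM (UMIs scaled to the library's total) in the higher library, at least 100 UMIs over both and a ratio of at least 2. Of 3932 genes with enough CPM and UMIs, 67 were at least 2-fold higher on the left and 33 on the right. These counts depended on the scaling. The median gene stood at a log2 ratio of 0.22 under CPM and 0.024 under median of ratios, which gave 41 left and 55 right genes. Totals without haemoglobin, mitochondrial and ribosomal genes gave 59 and 65, cells without the erythroid-like class 56 and 54, and an equal class makeup 29 and 24. Of the genes with a symbol, PALMD had the largest left ratio at 51.7 CPM against 2.25 (23.0-fold). CXCL14, PIP5K1B, MSC, RGMB, DENND5B, NR5A1, TGFBI, COL9A1, NKAIN4 and RIMS1 were 5.95-fold to 3.14-fold higher on the left. PALMD, CXCL14, MSC and NKAIN4 were among the 10 leading genes of a left cluster (1, 6 or 13). The genes named on the right were all among the leading genes of a cluster: AvBD10 (14.97-fold), RASSF2, SELENOP1 and RGN led the mesonephric-like cluster 18, and SLC4A1 the erythroid-like clusters. CEBPD, TCF21, UTS2B, KCNQ3 and TAGLN led clusters 7, 8, 10 or 23, so these ratios also describe the makeup of the libraries.

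The next comparison asked which genes differed between sides within the coelomic epithelium-like class, held by clusters 1, 6 and 11 on the left and 8 and 2 on the right. Of 4091 genes, 81 were at least 2-fold higher in its left cells and 95 in its right cells, and 95.7% of genes lay within 2-fold. NR5A1, a nuclear receptor gene of gonad development, stood at 105 CPM (100.4 to 109) against 20.5 (17.8 to 23.4). CYP26A1, whose product breaks down retinoic acid, stood at 89.5 CPM against 17.9. PALMD was 27.6-fold higher on the left and APCDD1L 14.1-fold. C2orf88, SERINC5, PIP5K1B, TGFBI, CXCL14, CCBE1 and PTBP3 were 8.08-fold to 4.10-fold higher. PALMD, APCDD1L, C2orf88, CXCL14 and CCBE1 were among the leading genes of clusters 1 or 6, so their ratios also describe how the clusters were drawn. On the right, CDH13 was 7.81-fold higher, and SYNPO2, ANTXR1, CEBPD, C4H4ORF32, SLC18A2, SDPR, PIEZO2, SCUBE1, NRARP and TFPI2 were 5.37-fold to 3.57-fold higher. CDH13 and ANTXR1 were leading genes of cluster 8, TFPI2 of cluster 2 and CEBPD of cluster 7. Of the gene lists, ALDH1A2, whose product makes retinoic acid, was higher on the right at 750.3 CPM against 328. WNT5A stood at 216 CPM on the right against 66.3, COL4A1 at 274 against 83.0, COL3A1 at 516 against 225 and CDH11 at 356 against 123. LTBP1 stood at 1225 CPM on the left against 553, FRZB at 158 against 58.5 and CDH3 at 124 against 60.7.

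**Figure D2:**
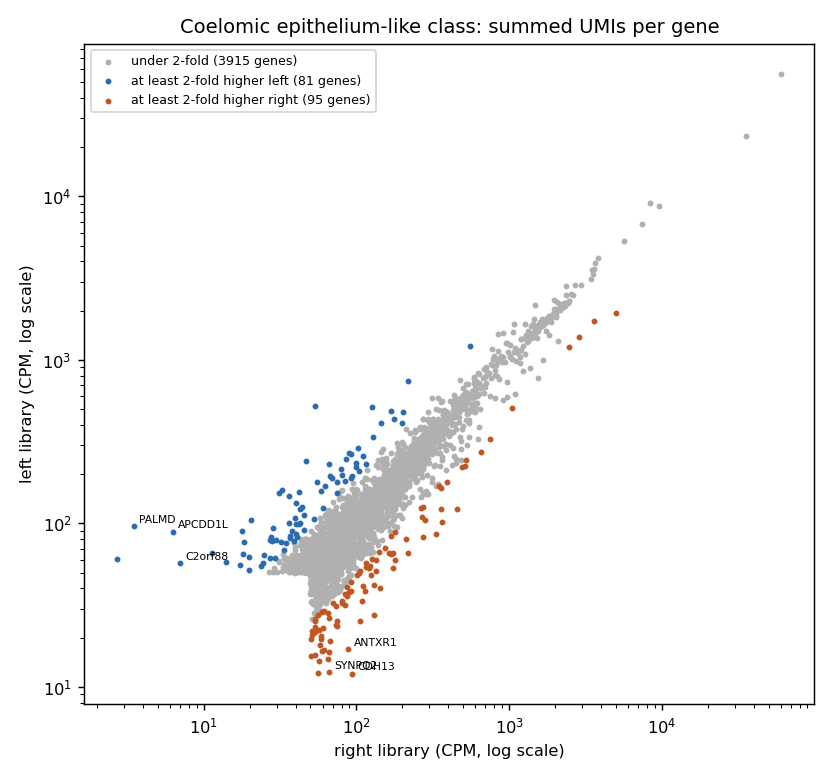
CPM of each gene in the right (x axis) and left (y axis) cells of the coelomic epithelium-like class, both on log scales, for genes with at least 50 CPM in the higher library and 100 UMIs over both. The 81 genes at least 2-fold higher on the left are blue and the 95 on the right orange, with some of the largest ratios labelled.

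Part of these differences went with the clusters. In cluster 4, with 1111 left and 1328 right cells, 73 of the 75 left genes measured and 90 of the 95 right genes kept the class's direction. Their median log2 ratios were 0.44 and -0.32 there, against 1.40 and -1.30 for the same genes over the class. In cluster 2, 67 of 81 left genes and 83 of 95 right genes kept the direction, as did 71 of 81 and 72 of 93 in cluster 11. Cluster 1 kept the direction for 61 of 81 and 75 of 95, and cluster 6 for 68 of 81 and 74 of 95. Supporting precursor-like cells, outside the class, shared it for 72 of 81 and 76 of 95 of these genes, so a shared direction alone does not show a difference within a cluster. Not every gene differed within a cluster: in cluster 1 NR5A1 stood at 160 CPM (152 to 168) on the left and 176 (133 to 230) in its 161 right cells. CYP26A1 stood at 129 CPM (122 to 136) and 163 (121 to 215) there. Elsewhere NR5A1 was higher on the left, with log2 ratios of 0.90 (0.51 to 1.30) in cluster 2, 2.05 (0.90 to 3.37) in cluster 4 and 0.88 (0.14 to 1.72) in cluster 6. CYP26A1 had log2 ratios of 0.81 (0.34 to 1.28) in cluster 2, 1.80 (0.79 to 2.92) in cluster 4 and 1.58 (0.41 to 3.06) in cluster 11. The intervals held 0 for NR5A1 in clusters 8 and 11 and for CYP26A1 in clusters 6 and 8.

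Within the gonadal mesenchyme-like class, held by clusters 5 and 9 on the left and 7 and 10 on the right, 43 of 4040 genes were at least 2-fold higher on the left and 54 on the right. Classes from resolution 0.5 turned this to 71 left and 53 right, and keeping called doublets gave 26 and 40. PIP5K1B, MGP, SLC5A7 and FAM110C were 6.14-fold to 4.06-fold higher on the left. CPNE8, CEBPD, ENPEP, ACE and TCF21 were 5.27-fold to 3.70-fold higher on the right. MGP, SLC5A7, CPNE8, CEBPD and TCF21 were leading genes of mesenchyme-like clusters, and ENPEP of an epithelium-like cluster. Of the gene lists, VCAN stood at 1063 CPM on the left against 399, TGFB2 at 2187 against 844, RDH10 at 101 against 34.1 and ISL1 at 110 against 38.9. On the right, COL3A1 stood at 1121 CPM against 380.3, ALDH1A3 at 287 against 80.1 and FGFR3 at 114 against 52.4. ISL1 led cluster 9, ALDH1A3 cluster 7, and VCAN, TGFB2 and ISL1 epithelium-like cluster 11, so these ratios also describe how the clusters were drawn. Over the class the left and right genes had median log2 ratios of 1.37 and -1.24. Within clusters the medians were smaller, at 0.68 and -0.72 in cluster 5, 0.73 and -0.89 in cluster 9, and 0.76 and -0.65 in cluster 10.

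The supporting precursor-like class, a single cluster of 2780 left and 2203 right cells, differed little: 99.8% of its 3957 genes lay within 2-fold, the same percent as in the germ cell-like and neural crest-like classes. Of its genes, 2 were at least 2-fold higher on the left, among them MSC (86.2 against 35.4). The 5 right genes were HBA1, HBBR, HBE, HBM and HBZ, all of them haemoglobin genes, which those cells are not expected to make. Haemoglobin took 0.994% of UMIs in the right cells of that class and 0.439% in the left. A single cluster groups cells of similar expression, so a small difference between its sides is partly built in. Single epithelium-like clusters ranged from 5 left and 3 right genes in cluster 4 to 67 and 58 in cluster 6, with 120 right cells. Contrasts of the supporting precursor-like class with classes of several clusters, here and below, are therefore not like for like.

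In the germ cell-like class 3 of 4567 genes were at least 2-fold higher on the left, among them MSC and AKR1D1, and 6 on the right, among them IL17RD, HBBR, HBE, HBM and HBZ. IL17RD stood at 141 CPM (128 to 156) in right cells and 66.3 (61.1 to 71.7) in left cells. The erythroid-like class had 7 left genes and 0 right genes, but 30 and 13 with totals that leave out haemoglobin, mitochondrial and ribosomal genes; the 5 with the largest ratios were MSC, GJA1, LTBP1, KRT7 and CDH2. In the endothelium-like class 20 genes were higher on the left, led by MSC, TRIM2, LHX9, EMX2 and NCAM1, and 11 on the right, led by H1F0, CA2, MMRN1, MYO1C and PROX1, a balance that turned to 3 left and 14 right genes under the stricter barcode filter. MSC was a leading gene of clusters 1, 6 and 19, TRIM2 and AKR1D1 of epithelium-like cluster 1, and H1F0 of erythroid-like cluster 12. CPM over all left cells exceeded the class's for 7 of 7 erythroid-like, 18 of 20 endothelium-like and 3 of 3 germ cell-like left genes. For right genes over all right cells it was 6 of 11 in the endothelium-like and 4 of 6 in the germ cell-like class. Free RNA of other cells may thus add to these ratios, which was not tested. In the neural crest or chromaffin-like class GJA1 and LTBP1 were higher on the left, and H1F0, TOMM40L, SDC3, PRNP and KIFC1L on the right. In the mesonephric epithelium-like class, with 122 left cells, 24 genes were higher on the left, led by NCAM1, JARID2, GJA1, PKM and RPAP3, and 91 on the right. Its right genes were led by CALB1 and SLC12A1, both with 0 left UMIs. They were 41.1-fold and 40.4-fold higher with the left set to a floor of 3 counts (exact intervals of the log2 ratio ending at -5.06 and -5.03). Those intervals take each UMI as a separate draw. How many right cells held these UMIs was not counted, so which cells the 122 left cells happened to include is not covered. TF, BSND and FXYD2 came next, BSND with 0 left UMIs and 81.7 CPM on the right.

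Shares of cells with a UMI of a gene were compared in cells thinned to 2000 UMIs, which left out 7210 left and 11927 right cells, so the cells compared also change. Neural crest or chromaffin-like cells gave the background. Median depths before thinning were 2543 left and 2317 right UMIs for the epithelium-like cells, and 3269 and 2907 for the neural crest-like cells. In thinned coelomic epithelium-like cells NR5A1 was found in 18.0% of left cells (17.1 to 19.0) and 3.96% of right cells (2.99 to 5.13), against 3.39% and 0.287% of neural crest-like cells. CYP26A1 was found in 14.2% (13.3 to 15.1) and 3.23% (2.35 to 4.31), against 5.09% and 0.287%. ALDH1A2 was found in 36.7% of left (35.5 to 37.9) and 62.0% of right cells (59.4 to 64.6), against 12.4% and 10.1%. Without thinning the epithelium-like shares were 19.0% and 3.23% for NR5A1, 15.5% and 2.69% for CYP26A1, and 40.3% and 61.3% for ALDH1A2. In supporting precursor-like cells the sides lay closer, with NR5A1 at 81.0 CPM on the left and 66.7 on the right, CYP26A1 at 81.0 and 77.9, and ALDH1A2 at 616 and 735.

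Gene lists fixed beforehand were placed among 10000 random lists matched on size and mean expression, a description of these libraries. Over all cells random lists had median log2 ratios near 0.20, and the left-right asymmetry list stood at 0.68 (percentile 100), with 12 of its 15 detected members above 0. The G2/M and S phase lists stood at 0.39 each (percentile 100 for both), with all 51 and all 42 members above 0, falling to 0.25 and 0.21 with an equal class makeup, and the germ cell list at 1.12 (percentile 100), which fell to 0.084 with an equal class makeup. The epithelium list stood at 0.37 (percentile 99.95), turning to -0.031 with an equal class makeup, and the hypoxia and glycolysis list at 0.31 (percentile 99.1), falling to 0.064 there. The mesenchyme and matrix list stood at -0.34, the HOX list at -0.27, the stress and dissociation list at -0.25 and the BMP and TGF-beta list at -0.12, each at percentile 0, although under the stricter barcode filter the mesenchyme list turned to 0.0098 and the BMP list to 0.092, and HOX rose to -0.047 and stress to -0.057. Summed CPM was higher on the left for the BMP list (3841 against 2996) and the stress list (6880 against 6105). It was lower on the left for the mesenchyme list (7834 against 9193) and HOX (856 against 959). The Hedgehog and Notch list (0.044, percentile 0.47) and the list of G1 regulators (0.035, percentile 0.67) were low against random lists. Their sign follows the scaling, since median of ratios put them at -0.14 and -0.15 by a shift that random lists share. The gonadal sex pathway list stood at 0.033 (percentile 2.59), FGF and ERK at 0.10 (6.23), apoptosis at 0.13 (13.3), retinoic acid at 0.15 (21.4), WNT at 0.18 (40.4), oestrogen and steroid at 0.22 (75.0) and the W-linked genes at 0.16 (31.1).

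Within the coelomic epithelium-like class, held by clusters 1, 6 and 11 on the left and 8 and 2 on the right, the asymmetry list stood at 0.65, G2/M at 0.42 and S phase at 0.40, all at percentile 100, although G2/M ranged from 0.19 after thinning to 0.82 with each library clustered alone. HOX stood at -0.50, mesenchyme and matrix at -0.49 and BMP and TGF-beta at -0.39, all at percentile 0. The summed CPM of the BMP and TGF-beta list went the other way, at 5124 on the left and 4314 on the right. The sums of HOX (1024 and 1352) and of mesenchyme and matrix (9697 and 12100) were lower on the left. S phase moved to 0.70 with each library clustered alone, mesenchyme and matrix to -0.75 at resolution 0.5 and BMP and TGF-beta to -0.26 after thinning. Within the gonadal mesenchyme-like class, held by clusters 5 and 9 on the left and 7 and 10 on the right, G2/M stood at 0.71, asymmetry at 0.57 and S phase at 0.54, again at percentile 100. There G2/M fell to 0.30 after thinning, 0.33 under the stricter barcode filter and 0.26 with clustering at resolution 0.5, and S phase to 0.35, 0.38 and 0.26. The HOX median of -0.15 (percentile 0.43) and mean of 0.15 differed in sign there. Mesenchyme and matrix stood at -0.34 and stress and dissociation at -0.18, both at percentile 0. The former weakened to -0.18 under the stricter barcode filter and -0.19 after thinning, and the latter moved to -0.40 with clustering at resolution 0.5, where asymmetry stood at 0.93. In the supporting precursor-like class the asymmetry list stood at 0.099 (percentile 95.2), S phase at 0.024 (76.0) and G2/M at 0.055 (99.6). Under the stricter barcode filter and after thinning all 3 turned negative, the asymmetry list to -0.016 and -0.027 and G2/M to -0.022 and -0.048. The germ cell list was high in each of these classes, at 0.89, 0.76 and 1.05, although the markers of these classes are somatic. In germ cell-like cells that list summed to 5900 CPM on the left and 6360 on the right. In these 3 classes its sums were low, at 172 and 114, 139 and 87.4, and 146 and 110 CPM. Free RNA of germ cell-like cells may add to these ratios, which was not tested. Outside these classes the asymmetry list stood at 0.79 (percentile 99.98) in erythroid-like, 0.40 (99.75) in neural crest-like and 0.34 (99.97) in germ cell-like cells. In mesonephric-like cells it stood at 0.44 (95.94) and in endothelium-like cells at 0.31 (88.42). A high value was thus not particular to the epithelium-like and mesenchyme-like classes.

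**Figure D3:**
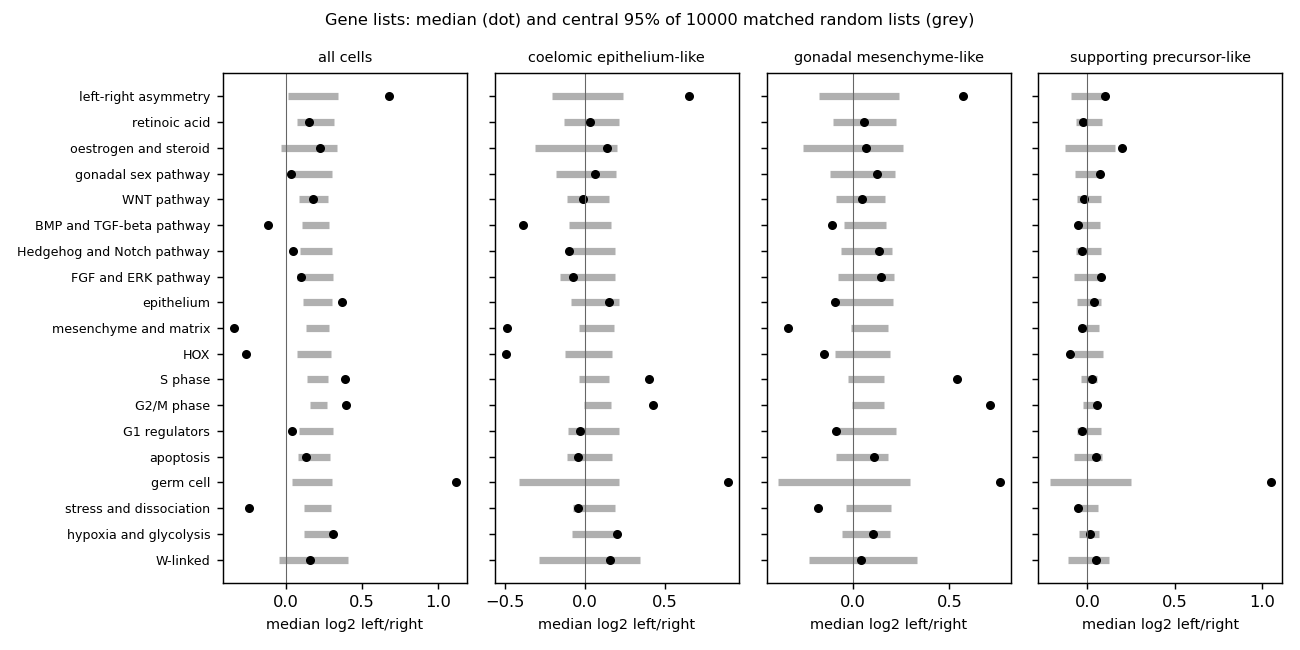
Median log2 ratio of left over right CPM (x axis) for each gene list (rows) over all cells and in 3 classes, with the central 95% of 10000 matched random lists in grey. Over all cells the left-right asymmetry list stood at 0.68 and the mesenchyme and matrix list at -0.34.

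The last comparison asked whether the sides differed in cell cycle genes. The share of thinned cells with at least 2 G2/M UMIs, set beforehand, was near its ceiling: 97.1% of left and 92.5% of right cells (96.6% and 88.5% without thinning). It separates few cells, so list levels are given too. The G2/M list summed to 7570 CPM on the left and 5779 on the right (1.31-fold). It was 1.35-fold higher on the left in coelomic epithelium-like cells (8062 against 5968) and 1.58-fold in gonadal mesenchyme-like cells (6700 against 4250). In thinned cells the means lay closer, at 16.9 and 15.15 G2/M UMIs per epithelium-like cell and 14.1 and 11.4 per mesenchyme-like cell. The medians did not, at 11 and 8 per epithelium-like cell and 8 and 5 per mesenchyme-like cell. Thinning also changed the cells compared, keeping 6091 of 9961 left but 1364 of 6246 right epithelium-like cells. An effect of depth was thus not told apart from that of the cells left out. In supporting precursor-like cells it stood at 9784 and 9506 CPM, and in germ cell-like cells at 8507 and 8321. At least 10 G2/M UMIs were found in 53.6% of left and 44.5% of right thinned epithelium-like cells, 43.8% and 33.2% of mesenchyme-like cells, and 64.0% and 65.9% of supporting precursor-like cells. Whether free RNA of cycling cells adds to these shares was not settled. CKS2, a member of the G2/M list, was a leading gene of epithelium-like cluster 6, which held 2117 left and 120 right cells. The epithelium-like difference may thus go in part with the clusters each library held. No list level within a cluster is given here. S phase shares with at least 2 UMIs were 94.2% of left and 86.8% of right thinned cells (93.3% and 83.6% without thinning).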

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

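All tests in this part were chosen after the results were seen. With 1 library per side, a difference between embryos or in dissection stays open beside every explanation below, and no test here separates it from the side.

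DCN went in opposite directions in different classes. It was higher on the right in coelomic epithelium-like cells (57.1 CPM left and 116 right, log2 ratio -1.02) and higher on the left in endothelium-like cells (137 and 51.6 CPM, log2 ratio 1.41). That the effects differ between the classes was not tested.

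Some clusters lay outside the class comparisons. Unnamed cluster 3 took 7.19% of left cells and cluster 13 took 5.60% of them, nearly all of cluster 13 being left cells. Cluster 15 took 2.81% of right cells and cluster 19 took 1.49% of left cells. Cluster 23, the smooth muscle-like cluster, took 0.206% of right cells and 0 left cells, but under other joint clusterings that class held cells of both sides, such as 1.49% of left and 1.63% of right cells at resolution 0.5. These shares lay above what a count of 0 allows, a limit that any cluster of such a size passes, so they show only that cells were left out of the class comparisons of genes.

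Germ cell-like cells took a larger share of the left library. Dilution in the right library by the cells classed here as blood or adjoining tissue cannot be the whole cause. Without them the log2 ratio of shares was 1.25 (1.05 to 1.44), against 1.44 with them. With 19806 of 21012 left and 16057 of 19410 right cells remaining, their removal could move the ratio only a little. Mesenchyme-like cluster 7, with 96 left and 2095 right cells, stayed in, and its runner-up class was nephrogenic or capsule mesenchyme. Dilution by adjoining tissue outside the removed classes is not covered by that removal. Loss of other cells at low depth was not tested. The limit to cells of at least 2000 UMIs, with a log2 ratio of 0.76, removes more right than left cells of other types and so lowers the ratio by construction. There were 28.5 germ cell-like cells per 100 supporting precursor-like cells on the left and 12.3 on the right, and 7.94 and 4.32 per 100 coelomic epithelium-like cells. A side difference in germ cell number may remain, as a hypothesis, beside a difference between embryos or in dissection.

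The genes at least 2-fold apart in the coelomic epithelium-like class may owe their ratios to the clusters each library holds, with free RNA adding a difference within each cluster. The shared direction within clusters does not decide this, since 72 of 81 left genes and 76 of 95 right genes also kept it in supporting precursor-like cells. For the left genes free RNA stays open within clusters 2 and 4, where their median CPM differences were 22.9 and 9.38, the lower being 0.665 of the largest in the 3 control classes (14.1, neural crest-like). In clusters 1 and 6, with 161 and 120 right cells, the left genes differed by 37.5 and 35.8 CPM, the lower being 2.54 times that control. The right genes in clusters 2 and 4 differed by 25.5 and 17.4 CPM, the lower being 2.76 times their largest control (6.31, neural crest-like). Both of these lay above their control, but that does not decide against free RNA. The genes were picked for their ratios in the class that holds these clusters, and the controls took no part in that. A larger difference in the clusters is thus partly built in. Free RNA also weighs more in shallow cells, and resampling takes genes that may vary together as separate. In UMIs per cell the 2 ratios were 1.08 (0.673 to 1.43 over resampled genes) and 0.743 (0.498 to 1.07), so in both cases free RNA cannot be told apart from a difference within clusters.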

How the results depend on the processing

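Chosen after seeing the data were the limit to cells of at least 2000 UMIs with the joint classes, the runs without blood or adjoining tissue (erythroid-, macrophage-, mesonephric-, interrenal-, neural crest- and smooth muscle-like classes and cluster 15), and the limits of 10 and 20 list UMIs. No paired analysis was possible because each side had 1 library and the labels pair no embryos. Leaving out a library and regrouping the samples did not apply. Setting apart cells with no G2/M UMI gave no value in any class, since each held under 100 such cells per library. Thinning to 4000 UMIs gave no value for the epithelium-like and mesenchyme-like classes, for lack of right cells. Except where stated, the cause of a move was not tested.

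Log2 ratios of named genes moved beyond their counting interval in 215 of 684 runs and reversed in 0. These genes were picked for large ratios in the same libraries, so the lack of reversals is largely built in. Class shares stayed within their interval in 70 of 113 runs, moved in 40 and reversed in 3, all 3 of the last for the supporting-like class. Log2 ratios of class shares are given next. Resolution 0.5 gave 0.40 for epithelium-like, -0.95 for erythroid-like and -0.080 for mesenchyme-like. Resolution 2 gave 0.14 for epithelium-like and -1.02 for mesenchyme-like. 15 principal components gave 0.76 for epithelium-like and -0.72 for mesenchyme-like. Called doublets kept gave 0.61 for epithelium-like and -0.81 for mesenchyme-like. Under the stricter barcode filter there were 0.83 for epithelium-like, -1.37 for endothelium-like, -1.82 for erythroid-like, 0.67 for germ-like, -0.38 for mesenchyme-like and -2.83 for mesonephric-like. There were also -1.95 for neural crest-like, -1.73 for interrenal-like and -0.28 for supporting-like. Thinning before clustering gave 1.27 for epithelium-like, -1.34 for endothelium-like, -2.06 for erythroid-like, 0.75 for germ-like, -0.27 for mesenchyme-like and -2.77 for mesonephric-like. There were also -1.85 for neural crest-like, -1.82 for interrenal-like and -0.22 for supporting-like. Each library clustered alone gave 1.23 for epithelium-like, -1.45 for erythroid-like, -0.43 for mesenchyme-like and 0.40 for supporting-like. 30 neighbours gave -0.94 for erythroid-like, -1.05 for mesenchyme-like and -3.25 for macrophage-like. 4000 variable genes gave -0.75 for mesenchyme-like. The use of all variable genes gave -0.63 for mesenchyme-like. Leaving out blood and adjoining tissue gave 0.37 for epithelium-like, -1.15 for mesenchyme-like and 0.033 for supporting-like. Cells of at least 2000 UMIs gave 1.28 for epithelium-like, -0.38 for mesenchyme-like, -0.28 for supporting-like and 0.76 for germ-like. The stricter filter and the thinned cells both leave out cells under 2000 UMIs, which removes more right than left cells.

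Counts of genes at least 2-fold higher stayed within 1.5 times the reported count in 60 of 97 runs on the left and 64 of 97 on the right. A lower CPM minimum or ratio admits more genes by construction. Median of ratios gave 41 left and 55 right (all). Totals without haemoglobin, mitochondrial and ribosomal genes gave 65 right (all), 30 left and 13 right (erythroid-like) and 5 left (germ-like). A minimum of 20 CPM gave 128 left and 77 right (all), 144 left and 182 right (epithelium-like), 77 left and 104 right (mesenchyme-like), 8 right (supporting-like), 28 left and 2 right (erythroid-like) and 11 left and 10 right (germ-like). Dropping the CPM minimum gave 499 left and 386 right (all), 327 left and 361 right (epithelium-like), 126 left and 166 right (mesenchyme-like), 9 left and 11 right (supporting-like), 45 left and 15 right (erythroid-like) and 35 left and 17 right (germ-like). A ratio of at least 1.5 gave 196 left and 85 right (all), 210 left and 272 right (epithelium-like), 179 left and 152 right (mesenchyme-like), 8 left (supporting-like), 16 left and 1 right (erythroid-like) and 14 left and 16 right (germ-like). There were also 86 left and 50 right (endothelium-like), 46 left and 69 right (neural crest-like) and 232 left and 294 right (mesonephric-like). Leaving out the erythroid-like class gave 54 right (all). Leaving out blood and adjoining tissue gave 53 right (all). An equal class makeup gave 29 left (all). Classes from each library clustered alone gave 151 left and 164 right (epithelium-like), 5 left (supporting-like) and 4 left (neural crest-like). Called doublets kept gave 26 left (mesenchyme-like), 2 right (erythroid-like), 5 left (germ-like) and 6 left (neural crest-like). Classes from resolution 0.5 gave 71 left (mesenchyme-like) and 26 left (erythroid-like). The stricter barcode filter gave 2 right (erythroid-like), 3 left (endothelium-like, from under 100 left cells and 853 genes) and 2 right (neural crest-like). Equal weight for every cell gave 15 left and 2 right (erythroid-like) and 8 right (neural crest-like). Thinning before summing gave 14 left and 3 right (erythroid-like), 8 left (germ-like) and 1 left and 1 right (neural crest-like).

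Differences between the sides in the share of cells with a UMI, in percentage points, kept their direction for NR5A1 in all runs over all cells and in the epithelium-, mesenchyme- and supporting-like classes. Thinning to 1000 UMIs gave 5.16 for NR5A1 (all), 4.64 for CYP26A1 (all), -7.98 for ALDH1A2 (all), 7.61 for NR5A1 (epithelium-like), 6.36 for CYP26A1 (epithelium-like) and 2.62 for CYP26A1 (mesenchyme-like). There were also -3.95 for ALDH1A2 (mesenchyme-like). Counting without thinning gave 11.2 for NR5A1 (all), 10.3 for CYP26A1 (all), 15.7 for NR5A1 (epithelium-like), 12.8 for CYP26A1 (epithelium-like), -21.03 for ALDH1A2 (epithelium-like) and -3.19 for ALDH1A2 (mesenchyme-like). There were also 5.07 for NR5A1 (supporting-like), 3.44 for CYP26A1 (supporting-like) and -0.490 for ALDH1A2 (supporting-like). Under the stricter barcode filter there were -6.29 for ALDH1A2 (all). Leaving out the erythroid-like class gave -10.3 for ALDH1A2 (all). Thinning to 1000 UMIs lowers these shares by construction.

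Differences in the share of cells with 2 or more cycle UMIs, again in percentage points, were 4.62 for G2/M and 7.40 for S over all cells as reported. Of 88 runs, 35 stayed within the interval, 51 moved and 2 reversed, both for G2/M in the supporting-like class. Thinning to 1000 UMIs gave 11.2 for G2/M (all), 12.2 for G2/M (epithelium-like), 15.4 for G2/M (mesenchyme-like), 2.68 for G2/M (supporting-like), 2.44 for G2/M (germ-like) and 11.3 for S (all). There were also 11.1 for S (epithelium-like), 16.4 for S (mesenchyme-like), 3.51 for S (supporting-like) and 0.0997 for S (germ-like). Counting without thinning gave 8.13 for G2/M (all), 10.2 for G2/M (epithelium-like), 12.8 for G2/M (mesenchyme-like), 2.82 for G2/M (supporting-like), 9.66 for S (all) and 10.8 for S (epithelium-like). There were also 16.5 for S (mesenchyme-like) and 1.87 for S (supporting-like). At least 1 UMI gave 1.53 for G2/M (all), 0.698 for G2/M (epithelium-like), 1.21 for G2/M (mesenchyme-like), 3.73 for S (all), 1.74 for S (epithelium-like) and 1.24 for S (mesenchyme-like). At least 3 UMIs gave 8.04 for G2/M (all), 7.81 for G2/M (epithelium-like), 7.81 for G2/M (mesenchyme-like), 1.78 for G2/M (supporting-like), 0.163 for G2/M (germ-like) and 10.5 for S (all). There were also 6.63 for S (epithelium-like) and 9.45 for S (mesenchyme-like). At least 10 UMIs gave 6.80 for G2/M (all), 9.13 for G2/M (epithelium-like), 10.6 for G2/M (mesenchyme-like), -1.89 for G2/M (supporting-like), 2.68 for G2/M (germ-like) and 8.996 for S (epithelium-like). There were also 6.84 for S (mesenchyme-like), -2.01 for S (supporting-like) and -1.54 for S (germ-like). The stricter barcode filter gave 3.13 for G2/M (all) and 4.41 for S (all). Leaving out the erythroid-like class gave 2.57 for G2/M (all) and 3.22 for S (all). Thinning to 4000 UMIs gave 0 for G2/M (supporting-like) and 8.49 for S (all). At least 20 UMIs gave -0.577 for G2/M (supporting-like), 1.09 for S (all), 0.561 for S (epithelium-like), 0.840 for S (mesenchyme-like) and 3.27 for S (germ-like). Called doublets kept gave 2.74 for G2/M (mesenchyme-like). With 2 UMIs nearly every thinned cell passed, so that limit has little room to show a difference.

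List medians stayed within their random spread in 613 of 760 runs, moved in 126 and reversed in 21. A change of sign counts as reversed only for a list that stood outside the central 95% of random lists as reported, and as moved or unmoved for the others. Over all cells, median of ratios and totals without haemoglobin, mitochondrial and ribosomal genes each lower every value by 1 shared shift, random lists included. The 30 moves and 4 reversals over all cells under these 2 scalings are therefore built in and say nothing of a list against random ones. Median of ratios gave 0.49 for left-right asymmetry, -0.038 for retinoic acid, 0.035 for oestrogen and steroid, -0.16 for gonadal sex, -0.013 for WNT, -0.31 for BMP and TGF-beta and -0.14 for Hedgehog and Notch. There were also -0.088 for FGF and ERK, 0.18 for epithelium, -0.53 for mesenchyme and matrix, -0.46 for HOX, 0.20 for S, 0.20 for G2/M and -0.15 for G1 regulators. There were also -0.057 for apoptosis, 0.93 for germ cell, -0.44 for stress and dissociation and 0.12 for hypoxia and glycolysis. Under the stricter barcode filter there were 0.95 for left-right asymmetry, 0.092 for BMP and TGF-beta, 0.0098 for mesenchyme and matrix, -0.047 for HOX, 0.28 for S, 0.25 for G2/M and 0.70 for germ cell. There were also -0.057 for stress and dissociation. An equal class makeup gave 0.51 for left-right asymmetry, 0.011 for WNT, -0.063 for Hedgehog and Notch, -0.058 for FGF and ERK, -0.031 for epithelium, 0.21 for S and 0.25 for G2/M. There were also -0.0098 for G1 regulators, -0.0018 for apoptosis, 0.084 for germ cell and 0.064 for hypoxia and glycolysis. Totals without haemoglobin, mitochondrial and ribosomal genes gave -0.0058 for retinoic acid, -0.12 for gonadal sex, 0.019 for WNT, -0.28 for BMP and TGF-beta, -0.11 for Hedgehog and Notch, -0.056 for FGF and ERK and 0.21 for epithelium. There were also -0.50 for mesenchyme and matrix, -0.42 for HOX, 0.23 for S, 0.24 for G2/M, -0.12 for G1 regulators, -0.025 for apoptosis and 0.96 for germ cell. There were also -0.40 for stress and dissociation and 0.15 for hypoxia and glycolysis. Leaving out blood and adjoining tissue gave 0.019 for retinoic acid, -0.18 for gonadal sex, -0.063 for WNT, -0.33 for BMP and TGF-beta, -0.092 for Hedgehog and Notch, -0.11 for FGF and ERK and 0.23 for epithelium. There were also -0.61 for mesenchyme and matrix, -0.48 for HOX, 0.31 for S, 0.30 for G2/M, -0.093 for G1 regulators, 0.83 for germ cell and -0.43 for stress and dissociation. There were also 0.16 for hypoxia and glycolysis. The mean in place of the median gave 0.18 for gonadal sex, -0.019 for BMP and TGF-beta, -0.081 for Hedgehog and Notch, 0.18 for epithelium, -0.24 for mesenchyme and matrix, -0.099 for HOX and -0.12 for G1 regulators. There were also 0.94 for germ cell, -0.15 for stress and dissociation and 0.21 for hypoxia and glycolysis. Leaving out the erythroid-like class gave 0.0054 for WNT, -0.31 for BMP and TGF-beta, -0.15 for Hedgehog and Notch, -0.074 for FGF and ERK, 0.17 for epithelium, -0.53 for mesenchyme and matrix and -0.46 for HOX. There were also 0.32 for G2/M, -0.051 for G1 regulators, -0.013 for apoptosis, 0.91 for germ cell, -0.43 for stress and dissociation and 0.12 for hypoxia and glycolysis. Dropping the barcode filter gave 0.22 for epithelium.

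Within the epithelium-like class the list medians moved as follows. The mean in place of the median gave 0.47 for oestrogen and steroid, -0.096 for epithelium and -0.19 for stress and dissociation. Thinning before summing gave -0.28 for WNT, -0.26 for BMP and TGF-beta and 0.19 for G2/M. The stricter barcode filter gave -0.0078 for epithelium and 0.28 for G2/M. Classes from resolution 0.5 gave -0.75 for mesenchyme and matrix, 0.51 for G2/M and -0.22 for stress and dissociation. Classes from each library clustered alone gave 0.70 for S, 0.82 for G2/M and -0.38 for stress and dissociation.

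Within the mesenchyme-like class they moved as follows. Classes from resolution 0.5 gave 0.93 for left-right asymmetry, 0.63 for oestrogen and steroid, -0.31 for BMP and TGF-beta, -0.13 for Hedgehog and Notch, 0.46 for epithelium, -0.49 for mesenchyme and matrix and 0.26 for S. There were also 0.26 for G2/M, 1.12 for germ cell and -0.40 for stress and dissociation. Equal weight for every cell gave -0.12 for retinoic acid. Members of at least 100 UMIs gave -0.15 for retinoic acid. Under the stricter barcode filter there were -0.035 for Hedgehog and Notch, 0.022 for epithelium, -0.18 for mesenchyme and matrix, 0.38 for S, 0.33 for G2/M and 1.10 for germ cell. Called doublets kept gave -0.23 for mesenchyme and matrix, 0.45 for S and 0.54 for G2/M. Thinning before summing gave -0.19 for mesenchyme and matrix, 0.35 for S and 0.30 for G2/M. Classes from each library clustered alone gave -0.24 for mesenchyme and matrix. The mean in place of the median gave -0.24 for mesenchyme and matrix and 0.15 for HOX.

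Within the supporting-like class they moved as follows. The stricter barcode filter gave -0.016 for left-right asymmetry, 0.039 for mesenchyme and matrix and -0.022 for G2/M. Equal weight for every cell gave 0.23 for left-right asymmetry. Thinning before summing gave -0.027 for left-right asymmetry, 0.34 for oestrogen and steroid, 0.029 for mesenchyme and matrix and -0.048 for G2/M. The mean in place of the median gave 0.38 for left-right asymmetry, -0.11 for Hedgehog and Notch, 0.0064 for HOX and -0.060 for hypoxia and glycolysis. Called doublets kept gave -0.10 for mesenchyme and matrix. Members of at least 100 UMIs gave 0.50 for germ cell.

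Depth limits what the smaller classes can show. The endothelium-like class held 262 left cells and the mesonephric-like class 122, and thinning to 2000 UMIs left 84 left endothelium-like cells. A gene with fewer than 100 UMIs over both libraries was not compared there.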

Other observations

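The values here were chosen after they were seen. Genes past the rule of size in the smaller classes were set against all cells of the same library. The CPM over all cells was higher than in the class itself for 7 of 7 left genes of the erythroid-like class, 18 of 20 left and 6 of 11 right genes of the endothelium-like class, and 3 of 3 left and 4 of 6 right genes of the germ cell-like class. So it was for 2 of 2 left and 1 of 5 right genes of the neural crest-like class, 9 of 24 left and 10 of 91 right genes of the mesonephric-like class, and all 7 genes of the supporting precursor-like class. Haemoglobin took 1.15% of UMIs in right and 0.562% in left coelomic epithelium-like cells.

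Barcodes outside the filter numbered 1595 on the left and 4017 on the right.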
